A study of Mus musculus with 15 samples.

How the data were processed

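The data are RNA-seq read counts of whole epididymides from 15 mice aged 7 weeks, 5 of each Plag1 genotype (WT, HET, KO), with 1 library per animal and no pooling. Per the labels' protocols, tissue was teased apart and washed in buffered saline against sperm, RNA was treated with DNase, and libraries were made from 2 µg of RNA with a stranded mRNA kit. The strain label reads Brown Swiss. The labels give no batch, litter, day or time of collection, and do not say what the animal numbers mean, so those numbers serve here as replicate names and, split at 700, as an alternative term.

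The deposited values are raw counts per gene, with 1 entry per NCBI Gene ID. Per the labels' processing notes, the authors used FastQC, HISAT2 2.0.5 and featureCounts of Subread 1.4.6p5 with build GRCm38.p6; the notes give no strand setting and no annotation release. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain. Of 41591 IDs, 40290 (96.9%) were named through a RefSeq gene table of GRCm38.p6, 84 through GENCODE metadata, and 1217 had no name. IDs outside the RefSeq table held 0.163% to 0.208% of the counts and stayed in the library sizes. Coordinates are those of that RefSeq table.

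Counts were tested as deposited with edgeR 4.0.16 (TMM factors, filterByExpr on the genotype, robust dispersion, quasi-likelihood test) in R 4.3.3, in 1 fit of all 15 libraries with a mean per genotype and 12 residual degrees of freedom. The contrasts were KO against WT, HET against WT, KO against HET, and HET against the midpoint of WT and KO on the log2 scale. P-values are two-sided and were adjusted by Benjamini-Hochberg over 19388 genes, with a threshold of 0.05; CPM values use TMM library sizes. Errors of log2 fold changes are SE from the fit. Libraries held 20.3 to 42 M counts, and shares of counts are given with a 95% Wilson interval where compared. The biological coefficient of variation was 16.3%. Counting noise is small beside it. Between libraries of 1 genotype the chi-square per degree of freedom ran from 6.28 to 19.69 in WT, from 5.57 to 32.14 in HET and from 20.78 to 94.34 in KO. The fit uses 1 dispersion per gene for all genotypes, so a wider spread in KO is averaged with that of WT and HET.

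Of 43 gene lists, 42 were tested with limma 3.58.1: camera on log2 CPM (prior count 2, preset correlation 0.01), camera with an estimated correlation, and fry. The list of mitochondrially encoded genes is not analysed here. Genes of each list were counted by the gene test over all genes and also adjusted over the list alone. Of the list genes 15 had no match and 5 were matched by a synonym. List scores are the mean log2 CPM of a list's tested genes minus the WT mean. The lists, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Plag1 and, per comparison, among genes past the threshold with at least 1 CPM in a group and an ordinary symbol, the 10 largest changes each way and the 5 smallest p-values each way; where 0 genes pass, the 5 smallest p-values each way as values; and up to 4 members of each list. Genes named outside the rule are said to be so.

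Alternatives were other scaling factors, leaving out the 20 most abundant genes, DESeq2 1.42.0, limma voom with quality weights, other filters on low counts, a fit of the 2 groups compared, the animal number range as a term or as a restriction, 1 surrogate variable from sva 3.50.0, and leaving out each library. Added after seeing the data were a fit without the libraries with over 1% ribosomal RNA genes and one with all libraries thinned to the smallest total. Single scores were compared by exact two-sided permutation of the libraries, and counts of genes by up to 100 other splits of the libraries. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

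The edgeR test was tested on simulated counts of 19164 genes with the real means and library sizes and 200 genes changed in KO. For KO against WT it recovered 64.2% of the 1.5-fold, 71.6% of the 2-fold and 90.9% of the 4-fold changes, with 5 false among 156 calls, and for HET against WT, where nothing was changed, it called 0. The simulated genes were independent and had the same dispersion in all genotypes. These rates therefore need not hold for the real libraries, which varied most within KO. Of 42 random lists camera and fry called 0, and a list of 34 raised genes was called by all 3 list tests. Genes of a random list need not vary together. In the real lists the estimated correlation ran from -0.056 (seminal vesicle and prostate) to 0.949 (skeletal muscle). Other splits of the real WT and KO libraries gave a median of 9 lists called by camera. The random lists therefore do not show how often camera with a preset correlation calls a real list of correlated genes.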

Results

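RNA from the whole epididymis of 15 mice aged 7 weeks was sequenced as stranded mRNA libraries. There were 5 wild-type mice (WT), 5 heterozygotes (HET) and 5 knockouts (KO) for Plag1, which encodes a zinc finger transcription factor, and each library came from 1 animal. Total counts ran from 20.3 to 27.8 M in WT, from 23.6 to 33.8 M in HET and from 25.3 to 42 M in KO. In all 15 libraries together, 19388 genes had enough counts to be tested. The comparisons address how gene expression in this organ, in which sperm mature and are stored, differs with the number of intact Plag1 alleles. On the first principal component of log2 CPM, which held 29.3% of the variance, 4 KO libraries lay between 26.8 and 48.5, while KO-738 lay at -17.8, within the WT range of -19.9 to -11.0. Ribosomal RNA genes took 1.289% of the counts of KO-738 (95% Wilson interval 1.286% to 1.293%) and 1.296% of those of HET-693 (1.292% to 1.300%), against at most 0.509% in the other libraries; these intervals cover counting error only.

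Plag1 (NCBI Gene 56711; GRCm38.p6 chromosome 4, 3898769 to 3938430) was lower in KO than in WT in every library. Its level was 12.7 ± 0.87 CPM (SD, n = 5) in WT, 10.2 ± 1.38 CPM in HET and 8.33 ± 0.97 CPM in KO, which puts HET at 80% and KO at 65.6% of WT. The 5 KO libraries held 7.0 to 9.38 CPM and the 5 WT libraries 11.96 to 14.03 CPM, from 211 to 344 Plag1 counts per library in these groups; the HET libraries held 8.12 to 11.84 CPM. KO-738 held 9.38 CPM. Plag1 fell by 0.61 ± 0.10 (SE) on the log2 scale from WT to KO (edgeR adjusted p = 0.00491), whereas the difference of HET from WT, -0.32 ± 0.10, had an adjusted p of 0.981 and that of KO from HET, -0.29 ± 0.10, one of 0.128. Counts cover the whole gene, and which part of it the knockout disrupts is not used here, so reads from intact exons check nothing.

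**Figure D1:**
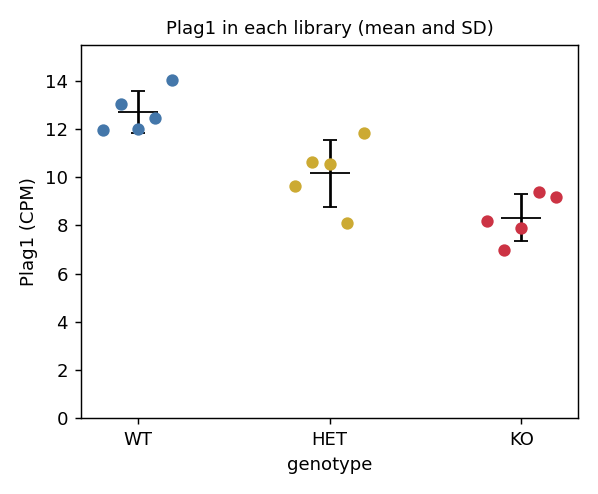
Plag1 level (CPM) in each of the 15 libraries by genotype, with the mean and SD of 5 libraries per genotype. All 5 KO libraries (7.0 to 9.38 CPM) lie below all 5 WT libraries (11.96 to 14.03 CPM).

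In KO against WT, genes of connective tissue, blood vessels and macrophages were higher. Of 25 measured fibroblast and collagen genes, 19 rose, 0 fell and 6 did not pass, with a median log2 fold change of 0.75. When p-values were adjusted over the list alone, given from here on as counts within the list, 23 rose. The matrix protein gene Sparc rose by 0.76 ± 0.11 (SE, on the log2 scale, as for all genes that follow, with 5 libraries per genotype), and the collagen genes Col6a3, Col6a1 and Col1a2 rose by 1.03 ± 0.17, 0.86 ± 0.16 and 0.91 ± 0.17. Of 12 endothelial genes, 10 rose and 2 did not pass (11 rose within the list, median 0.65), among them the junction protein gene Cdh5 (0.85 ± 0.12), Mmrn2 (0.75 ± 0.11), the clotting factor gene Vwf (0.54 ± 0.09) and Robo4 (0.74 ± 0.12). Of 17 macrophage genes, 11 rose and 6 did not pass (16 rose within the list, median 0.64), with Cx3cr1 at 0.64 ± 0.10, the growth factor receptor gene Csf1r at 0.65 ± 0.11, the protease gene Ctss at 0.52 ± 0.10 and the lysozyme gene Lyz2 at 1.01 ± 0.19.

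For these 3 groups the camera test with a preset correlation gave adjusted p-values of 2.62e-16 (fibroblasts), 2.67e-12 (endothelium) and 2.59e-12 (macrophages), and with a correlation estimated from the data, given below as estimated, it was 0.215 for each. The directional fry test gave 0.00361, 0.00166 and 0.00314. All WT animals are numbered above 700 and 3 KO animals below. With this number range as a term, 4 of 42 fibroblast and macrophage genes were called, against 30 without it (medians 0.62 and 0.69). KO-738 had scores (mean log2 CPM of a list minus the WT mean) of 0.13 for fibroblasts and 0.02 for macrophages, inside the WT ranges, whereas the other 4 KO libraries had 0.58 to 0.97 and 0.70 to 0.84. Its endothelial score of 0.44 lay above the highest WT score of 0.09. Smooth muscle genes, another non-epithelial group, had a median of 0.10 with 0 of 15 passing (0 within the list, camera adjusted p = 0.167).

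**Figure D2:**
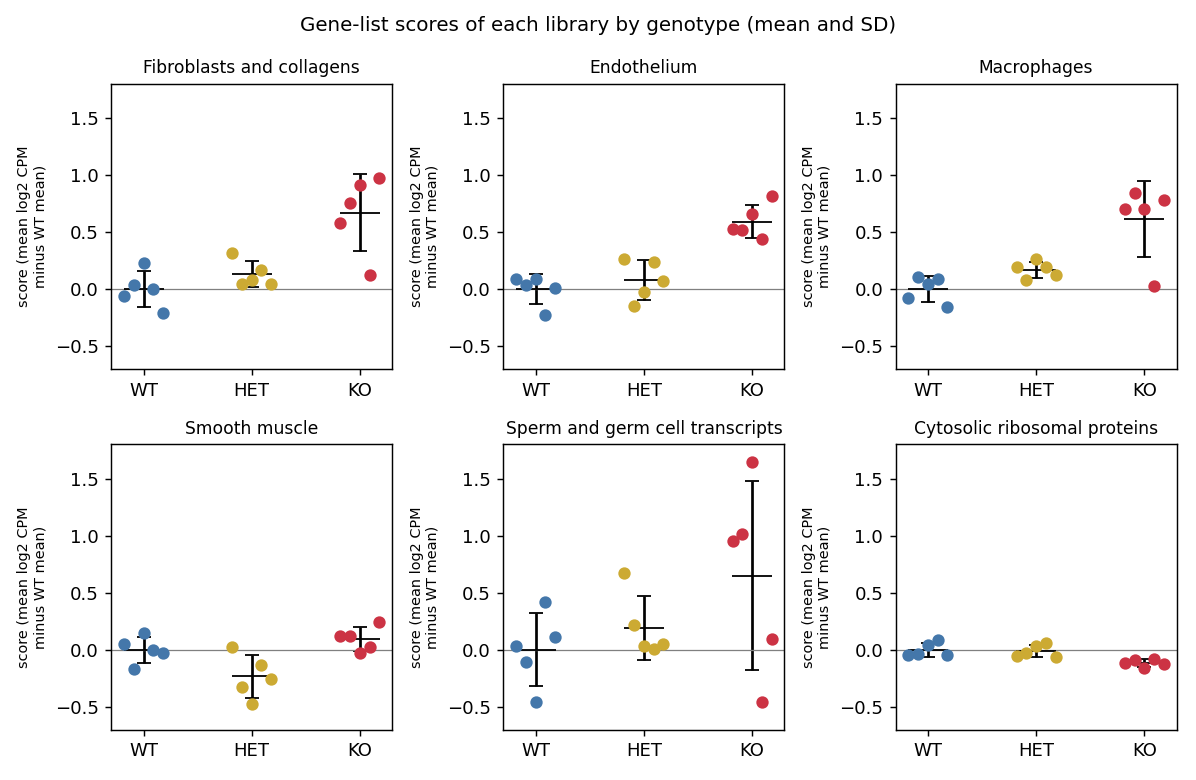
Scores of 6 gene lists (mean log2 CPM of the list's genes minus the WT mean) in each library by genotype, with the mean and SD of 5 libraries. KO-738 is the low KO library in the fibroblast (0.13) and macrophage (0.02) panels, and KO-694, KO-695 and KO-696 are the high ones for sperm and germ cell transcripts (0.95, 1.01 and 1.65).

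Of 21 growth and imprinted genes, 5 rose in KO against WT and 16 did not pass, and 15 of the 21 had a positive value (7 rose within the list, median 0.29, camera adjusted p = 0.00367, estimated 0.215). The growth factor gene Igf1 rose by 1.19 ± 0.16, from 25.6 ± 2.83 CPM (SD) in WT to 58.6 ± 14.9 CPM in KO, with 32.5 CPM in KO-738. The genes of its binding proteins Igfbp4 and Igfbp3 rose by 0.68 ± 0.11 and 0.56 ± 0.10, and the imprinted genes Peg3 and Grb10 rose by 0.39 ± 0.08 and 0.48 ± 0.11. Grb10, like Ldhc, Rpl39l and the KO against HET value of Igfbp3 in what follows, was named after its value was seen. In the PLAG family, 2 of 3 genes fell (2 within the list, camera adjusted p = 0.00674, estimated 0.215): Plag1 itself and Plagl1 (-0.32 ± 0.08, adjusted p = 0.0371), while Plagl2 had a value of -0.08 ± 0.06. The fall of Plag1, the targeted gene, enters the result of this list in every comparison. Plagl1 was not called in 11 of 15 fits without 1 library. Serpins had 6 of 29 higher and 1 lower (9 and 1 within the list, camera adjusted p = 0.0215, estimated 0.215, and 0.0569 without KO-738), with Serpina3c at 1.48 ± 0.25 and the complement inhibitor gene Serping1 at 0.60 ± 0.12; Serpina3c belongs to a family of near copies, so its counts are uncertain.

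By their list score, transcripts of germ cells were higher in 3 of the 5 KO libraries. Of 28 sperm and germ cell genes, 5 rose and 23 did not pass (10 rose within the list, median 0.84, camera adjusted p = 1.75e-05, estimated 0.493). Among the animals numbered 700 and above the direction turned to lower in KO (0.0912). Ddx4, an RNA helicase gene of the germ line, rose by 1.95 ± 0.45, Fabp9 by 1.72 ± 0.40, Akap3 by 1.89 ± 0.46, Meig1 by 1.32 ± 0.33 and the lactate dehydrogenase gene Ldhc by 1.70 ± 0.42. All of these named genes were above every WT library in KO-739 too, such as Ldhc at 20.6 CPM against at most 9.38 CPM in WT. In KO-738 each of them lay within the WT range. The germ cell score was 0.95, 1.01 and 1.65 in KO-694, KO-695 and KO-696, -0.46 and 0.10 in KO-738 and KO-739, and at most 0.42 in WT. These 3 KO animals carry numbers below 700, as do HET-692 and HET-693, while all WT animals are numbered above 700. ADAM proteases, of which several are sperm proteins, had 7 of 22 higher (8 within the list, median 0.47, camera adjusted p = 0.000207, estimated 0.343), including Adam19 (0.69 ± 0.12), Adam12 (1.10 ± 0.24), Adam23 (1.08 ± 0.25) and Adam5 (1.42 ± 0.34). Of 20 genes of ciliated efferent duct cells, 2 rose, Fam183b (0.98 ± 0.26) and Tekt1 (1.07 ± 0.30), and 5 within the list (camera adjusted p = 0.00437, estimated 0.493). For them it was 0.0799 without KO-695, and among the animals numbered 700 and above the direction turned (0.759). Cell cycle genes had a median of 0.80, but 0 of 26 passed over all genes and 16 were higher within the list (camera adjusted p = 1.16e-06, estimated 0.493). The cyclin genes Ccnb2 and Ccnb1 had values of 1.21 ± 0.38 and 1.19 ± 0.37, and of 0.778 and 0.685 without KO-695. The cell cycle score was 1.35 in KO-695 and 0.13 to 0.63 in the other KO libraries.

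Markers of neighbouring tissues were high in some KO libraries. Skeletal muscle genes had a score of 7.3 in KO-739 against 0.12 to 0.55 in the other KO libraries, with the myosin gene Myh1 at 899 CPM there; 0 of 11 passed and 11 were higher within the list (camera adjusted p = 0.0136, 0.509 with an estimated correlation, and 0.401 without KO-739). Adipocyte genes had 1 of 15 higher, the lipase gene Lpl (2.03 ± 0.42), with 8 higher and 1 lower within the list (camera adjusted p = 0.0202, estimated 0.493); the adipocyte score was 0.94 in KO-694, 2.30 in KO-695 and 1.24 in KO-738 against at most 0.76 in WT, and the camera adjusted p was 0.191 without KO-695 and 0.134 without KO-738. Without WT-719, KO-694 or KO-739 the camera adjusted p of nerve and glia genes was 0.072, 0.0523 or 0.0626. These genes had 2 of 11 higher, Scn7a (0.56 ± 0.14) and Pmp22 (0.37 ± 0.10), with 4 higher and 1 lower within the list (camera adjusted p = 0.0215, estimated 0.343). Of 24 interferon response genes, the antiviral gene Rsad2 (0.88 ± 0.17) and Gbp2 (0.56 ± 0.14) rose, 3 within the list (camera adjusted p = 0.00437, estimated 0.493, and 0.0692 without KO-696). Basal cell genes had 0 of 11 passing, also within the list (camera adjusted p = 0.0366, estimated 0.493). Without WT-723, WT-726, KO-695, KO-696 or KO-738 their camera adjusted p was 0.0847, 0.104, 0.0906, 0.0549 or 0.142.

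Other lists had a lower camera result. Of 82 cytosolic ribosomal protein genes, 6 fell and 1 rose (8 and 1 within the list), with a median of -0.13, and Rpl27 and Rpl23a at -0.25 ± 0.06 and -0.19 ± 0.05 (camera adjusted p = 4.45e-07, estimated 0.354); pseudogenes can share the reads of this family, so single members are uncertain. The member that rose was Rpl39l (1.62 ± 0.46), a relative of Rpl39 that is known from the testis. Cholesterol synthesis genes had a median of -0.15 with 0 of 20 passing, also within the list (camera adjusted p = 0.00329, estimated 0.493). Of 25 genes of the unfolded protein response, the chaperone gene Dnajb9 fell by 0.25 ± 0.07, and 1 fell within the list (camera adjusted p = 0.0124, estimated 0.493).

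Most genes of the regional programme of the epididymis did not pass, and these lists had no camera result under 0.05. By directional fry, fluid transport (lower) and the retinoid pathway (higher) had an adjusted p of 0.0327 each. Without regard to direction, fry gave 9.26e-05 for corpus and cauda and for the retinoid pathway, 5e-04 for duct growth and 0.000619 for fluid transport. It gave 0.00281 for clear cells, 0.00731 for antioxidants, 0.00923 for junctions, 0.0122 for androgen response and 0.0406 for beta-defensins. Initial segment (0.122), caput (0.159), lipocalins (0.602) and RNases (0.675) did not pass it. In the caput list 0 of 22 genes passed, among beta-defensins 0 of 36 and among lipocalins 0 of 7, all also within the list. Among the epididymal RNases 0 of 5 passed (1 lower within the list). In the initial segment list 2 of 25 rose, the defensin-like gene Spag11b (0.59 ± 0.10; a gene with a close relative, and so uncertain) and Nell2 (0.96 ± 0.25), with 2 higher and 1 lower within the list. In the corpus, cauda and vas deferens list the uroplakin gene Upk1b (0.58 ± 0.10) and the keratin gene Krt20 (1.68 ± 0.32) rose and the anion exchanger gene Slc26a3 (-0.35 ± 0.10) and Hoxd10 (-0.60 ± 0.17) fell, of 18 measured (3 and 4 within the list). Among 37 antioxidant enzymes Gpx6 (0.97 ± 0.22) and Sod3 (0.57 ± 0.16) rose and Gpx4 (-0.28 ± 0.08) and Gpx3 (-0.67 ± 0.19) fell (3 and 2 within the list). Of 15 fits without 1 library, 4 did not call Gpx6, 13 did not call Sod3, 13 did not call Gpx4 and 14 did not call Gpx3. Gpx3 stood at 3480 CPM in KO-738, inside the WT range. The androgen response list had Sord higher (0.51 ± 0.13) and Azgp1 lower (-1.28 ± 0.30) of 22 (1 and 1 within the list). Fluid transport genes had the water channel gene Aqp5 (-0.73 ± 0.15) and the carbonic anhydrase gene Car4 (-0.63 ± 0.16) lower of 24 (2 higher and 6 lower within the list). Clear cells had the proton pump gene Atp6v1c2 (-0.53 ± 0.13) and Dmrt2 (-0.33 ± 0.09) lower of 9 (1 higher and 2 lower within the list), and junctions had Cldn8 (-0.31 ± 0.07) lower of 18 (2 lower within the list). Duct growth genes had the Wnt antagonist gene Sfrp1 (0.71 ± 0.12) and Fgf10 (0.78 ± 0.15) higher and Sfrp2 (-0.79 ± 0.16) lower of 27 (2 and 1 within the list). The retinoid pathway had the synthesis enzyme gene Aldh1a2 (0.88 ± 0.12) and Dhrs3 (0.25 ± 0.06) higher of 17 (3 within the list).

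Among the remaining lists, testis somatic cells had Wt1 (1.84 ± 0.27) and Aard (0.85 ± 0.14) higher of 7 (3 higher and 1 lower within the list, fry adjusted p = 0.00267, camera 0.0661). Lymphocytes had the B cell genes Cd79b (1.45 ± 0.29) and Ighm (1.79 ± 0.43) higher of 10 (2 within the list). Both are near the floor of detection. Cd79b held 0.115 to 0.215 CPM in WT, 0.255 to 0.53 CPM in HET and 0.28 to 0.508 CPM in KO. Ighm held 0.163 to 0.538 CPM in WT, and 5 of 15 fits without 1 library did not call it. Antigen presentation had 4 of 16 higher, Tap1 (1.01 ± 0.25), Cd74 (0.49 ± 0.13), Ciita (0.81 ± 0.22) and H2-Eb1 (1.01 ± 0.28), with 4 higher and 1 lower within the list. H2-Eb1 had 10.5 CPM in KO-738 against 3.16 to 4.18 CPM in the other KO libraries. Its value was 0.56 without KO-738 (adjusted p = 0.00942), and 12 of 15 fits without 1 library did not call it. Of 11 tested genes listed by name as neighbours of Plag1, the enkephalin gene Penk rose (0.56 ± 0.08), with 1 higher and 1 lower within the list. This list was not limited by position to chromosome 4. In the lists of WFDC and SPINT inhibitors (19 genes), immediate early genes (21), oxidative phosphorylation (38), neutrophils (5), blood cells (4) and seminal vesicle and prostate (6), 0 genes passed. Within the list, the first had 1 higher and 3 lower, the last 2 higher and 1 lower, and the others 0. The median, mean and camera direction differed in sign for corpus and cauda, oxidative phosphorylation, beta-defensins, caput, duct growth, neutrophils and neighbours of Plag1.

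Among genes with at least 1 CPM in a group and an ordinary symbol, the largest rises included markers of the tissues above. Car3, a carbonic anhydrase gene of muscle and fat, rose by 4.6 ± 1.22, with 803 CPM in KO-739 and 116 CPM in KO-695. Without KO-739 its value was 2.55 (adjusted p = 0.0912), and 12 of 15 fits without 1 library did not call it. The renin gene Ren1 rose by 3.43 ± 0.60, with 1.82 to 5.71 CPM in 4 KO libraries and 0.314 CPM in KO-738, inside the WT range; the genome of some strains carries a close copy, so its counts are uncertain. Gtsf1l (3.07 ± 0.65), Ccdc63 (2.45 ± 0.65), Kif2b (2.38 ± 0.53), Tex33 (2.36 ± 0.59) and Ccer1 (2.35 ± 0.58) rose, each with its 3 highest libraries in KO-694, KO-695 and KO-696. Cnmd rose by 2.78 ± 0.59, Dusp13 by 2.58 ± 0.57 and Ctla2a by 2.35 ± 0.46, the last with 236 CPM in KO-739 and a value of 1.70 without it. Cnmd was highest in the animals numbered below 700, HET included. HET-692, HET-693, KO-694, KO-695 and KO-696 held 4.13 to 11.6 CPM, and the other libraries at most 3.11 CPM. Without KO-696 Gtsf1l had 2.45 and Tex33 had 1.75 (adjusted p = 0.0854). The trehalase gene Treh (-2.37 ± 0.49), Kap (-1.98 ± 0.40), Mrps18b (-1.71 ± 0.47), Slc25a33 (-1.45 ± 0.38), Tmem254c (-1.19 ± 0.34), the ion channel gene Mcoln3 (-1.14 ± 0.18), the metalloprotease gene Mep1a (-1.13 ± 0.27), Pappa2 (-1.11 ± 0.26) and Get1 (-1.10 ± 0.31) fell the most within this limit, with Azgp1. Mrps18b had 4.73 CPM in WT-726 and its value was -0.98 without that library (adjusted p = 0.0944). Below 1 CPM, Evx1os (-3.61 ± 0.38, adjusted p = 0.000821) and Evx1 (-3.53 ± 0.57), chosen after their values were seen, fell further. The smallest p-values within the limit belonged to Tenm3 (0.82 ± 0.09), Rflnb (0.75 ± 0.08), Steap4 (0.76 ± 0.10), Aldh1a2 and Penk among rises, and to Hoxb9 (-0.46 ± 0.07), Mcoln3, Bglap3 (-0.73 ± 0.12), Plag1 and Slit1 (-0.66 ± 0.12) among falls. Tenm3 and Rflnb had an adjusted p of 0.000821. Tmem254c is a member of a family of near copies and its counts are uncertain.

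**Figure D3:**
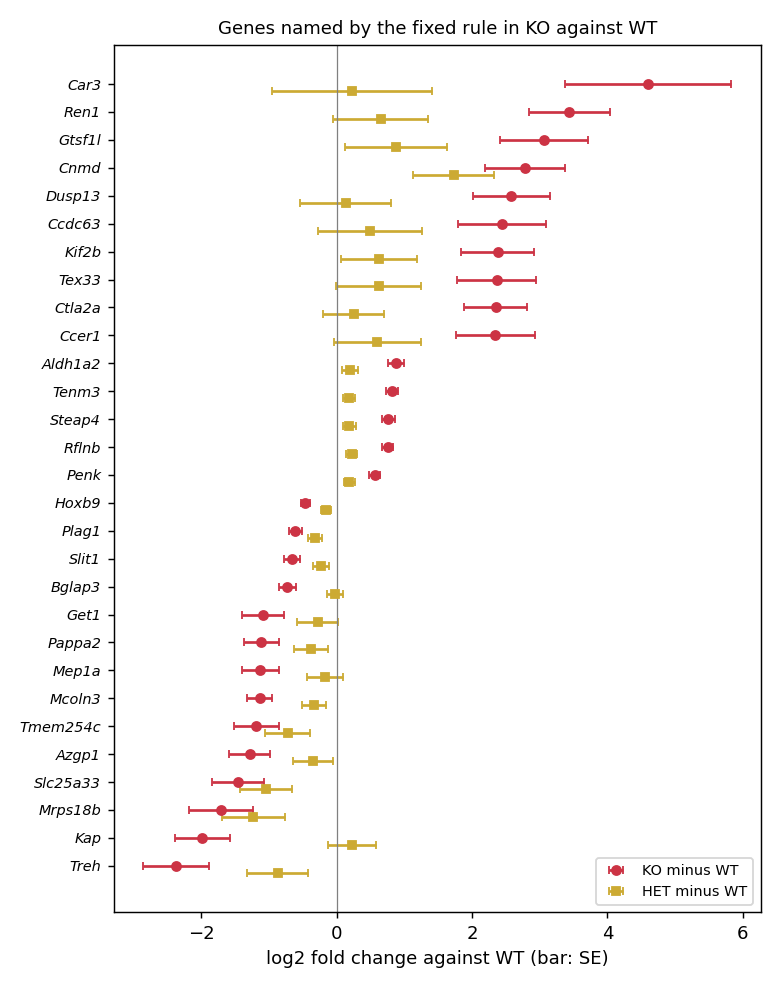
Log2 fold changes against WT (points) with their SE (bars) for Plag1 and for the genes of at least 1 CPM that the fixed rule names in KO against WT by size of change or p-value, without those it names as list members, in KO (5 libraries) and HET (5 libraries). The KO values shown run from -2.37 for Treh to 4.6 for Car3.

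Of 15 genes of the circadian clock, chosen after the values of Dbp and Per2 had been seen, 5 differed between KO and WT. The clock output gene Dbp (-0.76 ± 0.15, adjusted p = 0.0137), Per2 (-0.63 ± 0.13, 0.0165) and Ciart (-0.56 ± 0.14, 0.033) fell, and the activators Arntl (0.49 ± 0.10, 0.0104) and Npas2 (0.78 ± 0.19, 0.0292) rose. The others did not pass: Per1 (-0.24), Per3 (-0.40), Nr1d1 (-0.14), Nr1d2 (-0.33), Tef (-0.35), Hlf (-0.40), Bhlhe41 (0.10), Clock (0.01), Nfil3 (0.27) and Cry1 (-0.06), with adjusted p-values from 0.0555 for Tef to 0.951 for Clock. The time of day of collection is not in the labels.

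**Figure D4:**
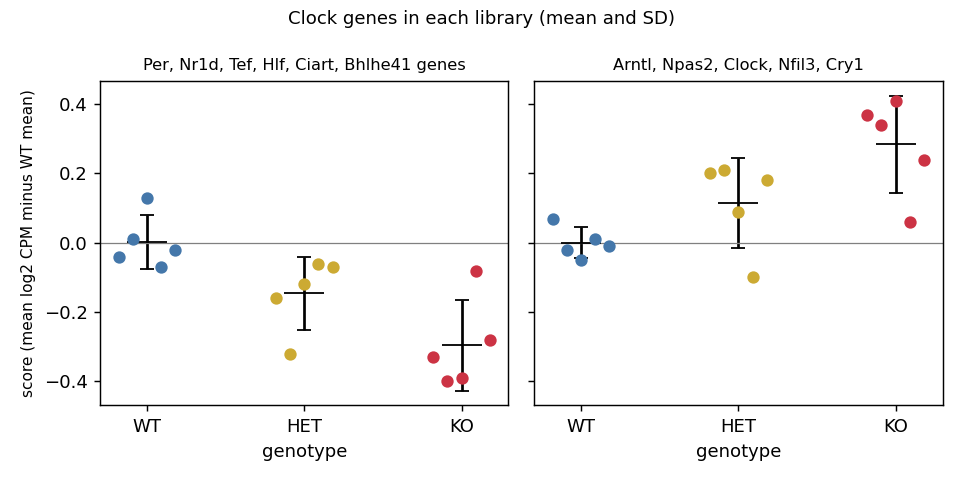
Scores of clock genes (mean log2 CPM minus the WT mean) in each library by genotype, with the mean and SD of 5 libraries; the left panel holds 8 genes of the Per, Nr1d and Dbp-like arm and the right panel 5 genes of the Arntl arm. The mean KO score was -0.29 in the left and 0.29 in the right panel; KO-738 lay at -0.08 and 0.06.

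In all, 1163 genes differed between KO and WT at an adjusted p under 0.05 (edgeR), 853 higher and 310 lower, and 277 of them by at least 2-fold (243 higher, 34 lower). By camera 18 of 42 gene lists passed, 0 of them with an estimated correlation, and 12 lists passed fry, 9 of them among the 18. Of these 18 lists 7, and of the 104 named genes with a call 53, lost it in at least 1 fit without a library. The least stable were Gpx3, Tekt1 and Rpl39l, not called in 14 of 15 such fits. Next came Sod3, Gpx4, Get1, Slc26a3 and Pmp22, not called in 13. Without WT-709, WT-719, WT-720, WT-723 or WT-726 the count was 435, 535, 601, 444 or 636, and without KO-694, KO-695, KO-696 or KO-738 it was 677, 565, 318 or 2923. It was 176 with the animal number range as a term and 0 among the animals numbered 700 and above (edgeR, 3073 at an unadjusted p under 0.05, other tools not run), where KO had 2 libraries. A fit of only the WT and KO libraries gave 287 while DESeq2 gave 1982.

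In HET against WT, which asks what the loss of 1 allele does, the smallest p-values belonged to Cd79b (1.39 ± 0.30), Adap2 (0.57 ± 0.14), the sodium exchanger gene Slc9a4 (0.49 ± 0.13), Brwd1 (0.34 ± 0.09) and Chd1l (0.19 ± 0.05) among positive values. Among negative ones they belonged to the antisense transcript Evx1os (-1.65 ± 0.31), the actin-binding gene Pfn1 (-1.27 ± 0.28), Vwa2 (-1.01 ± 0.24), Upb1 (-0.66 ± 0.16) and Id1 (-0.58 ± 0.14), each of the 10 with an adjusted p of 0.981. Pfn1 ranged from 9.69 to 36.2 CPM within WT and has pseudogenes that can share its reads, and Evx1os overlaps Evx1 with an unknown strand setting of the counting, so both are uncertain. By edgeR 0 genes differed, 854 had an unadjusted p under 0.05, DESeq2 called 1 gene (Pfn1, adjusted p = 0.04) and limma voom 0. Smooth muscle genes had a median of -0.20 (0 of 15 passing, 1 lower within the list, camera adjusted p = 8.96e-07, estimated 0.512), and macrophage genes one of 0.17 (0 of 17 passing, 0 within the list, 0.00387, estimated 0.676). Fibroblast genes had a median of 0.12 (0 of 25 passing, 0 within the list, 0.0212, estimated 0.833).

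In total 11 lists passed camera in HET against WT, 0 with an estimated correlation and 0 with fry. Beside those given, duct growth (median -0.11, estimated-correlation adjusted p = 0.512), immediate early genes (-0.10; 0.541) and the PLAG family (-0.14; 0.512) had a lower direction. The direction was higher for cell cycle (0.21; 0.833), beta-defensins (0.11; 0.676), lymphocytes (0.20; 0.512), caput (0.09; 0.512) and initial segment genes (0.09; 0.724). Of these lists 0 genes passed over all genes. The cell cycle direction turned with the number range as a term (0.671) and among the animals numbered 700 and above (0.844), and its camera adjusted p was 0.563 without HET-692 and 0.0799 to 0.0887 without WT-719, WT-720 or WT-726. Adjusted over the list alone, duct growth and the PLAG family had 1 lower each, lymphocytes 2 higher, and the others 0. Without WT-726 the number of lists was 6 and without HET-692 it was 7, and 7 of the 11 lists lost their call in at least 1 fit without a library. For fibroblasts the adjusted p was 0.28 without WT-726 and 0.237 without HET-692. Against the midpoint of WT and KO, the value expected if each allele added the same amount on the log2 scale, HET differed in 0 genes by edgeR (1522 at an unadjusted p under 0.05, smallest adjusted p 0.498), in 24 by DESeq2 and in 1 by limma voom (Kank2, -0.37, adjusted p = 0.042, named after its value was seen).

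The comparison of KO against HET uses the same 5 KO libraries as KO against WT, so the 2 are not independent. Of 25 fibroblast and collagen genes, 9 rose (21 within the list, median 0.61, camera adjusted p = 6.66e-14, estimated 0.253), with the fibronectin gene Fn1 at 0.63 ± 0.12, Col6a3 at 0.90 ± 0.17 and Sparc at 0.54 ± 0.11. Of 12 endothelial genes, 8 rose (10 within the list, median 0.61, 2.05e-11, estimated 0.234), with Mmrn2 at 0.70 ± 0.11, Vwf at 0.54 ± 0.09 and Cdh5 at 0.68 ± 0.11. Of 17 macrophage genes, 3 rose (14 within the list, median 0.41, 6.55e-09, estimated 0.253), with the mannose receptor gene Mrc1 at 1.14 ± 0.24, Csf1r at 0.47 ± 0.11 and Mpeg1 at 0.41 ± 0.10. Of 21 growth and imprinted genes, 5 rose, Igf1 (0.88 ± 0.16), Igfbp4 (0.54 ± 0.11), Ndn (0.54 ± 0.11), Peg3 (0.39 ± 0.08) and Igfbp3 (0.40 ± 0.10), with 13 higher and 1 lower within the list (5.7e-05, estimated 0.147).

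Smooth muscle genes had 2 of 15 higher in KO than in HET, Synpo2 (0.47 ± 0.11) and Lmod1 (0.30 ± 0.07), and 11 within the list (camera adjusted p = 1.6e-06, estimated 0.253). ADAM proteases had Adam12 (1.14 ± 0.23) and Adam19 (0.56 ± 0.12) higher of 22 (8 within the list, 7.62e-05, estimated 0.298). Cytosolic ribosomal proteins had Rpl23a (-0.22 ± 0.05) and Rpl7a (-0.28 ± 0.06) lower of 82 (15 within the list, 2.21e-08, estimated 0.298). Sperm and germ cell genes had a median of 0.54 with 0 of 28 passing (6 within the list, 0.00112, estimated 0.54, and 0.128 without KO-696). Among the animals numbered 700 and above they were lower in KO, with a camera adjusted p of 0.0177. Single genes from other lists that rose were Aldh1a2 (0.68 ± 0.12), Wt1 (1.21 ± 0.26), Penk (0.37 ± 0.08), Sfrp1 (0.55 ± 0.12), Fgf10 (0.64 ± 0.15), the water channel gene Aqp1 (0.59 ± 0.13), Tap1 (1.0 ± 0.24), Rsad2 (0.87 ± 0.16), Serpina3n (0.48 ± 0.11) and Wfdc1 (0.47 ± 0.11). Serpina3n belongs to a family of near copies and is uncertain.

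The other lists with a higher camera result in KO than in HET, each given with its median log2 fold change and its adjusted p with an estimated correlation, were the cell cycle (0.47; 0.53), ciliated cell (0.32; 0.441), adipocyte (1.49; 0.441), skeletal muscle (4.86; 0.53), basal cell (0.15; 0.336), retinoid pathway (0.22; 0.253), antigen presentation (0.57; 0.253), nerve and glia (0.32; 0.298), duct growth (0.10; 0.348) and serpin (0.23; 0.253) genes. Lists with a lower one were the cholesterol synthesis (-0.14; 0.441), unfolded protein response (-0.09; 0.351), WFDC and SPINT inhibitor (-0.11; 0.416), RNase (-0.20; 0.298) and beta-defensin (-0.06; 0.507) genes. Over all genes these lists had at most 2 members passing, those named above. Within the list 11 were higher for skeletal muscle, 8 higher and 1 lower for adipocytes, 4 higher and 1 lower for the retinoid pathway, and 4 higher for antigen presentation. There were 3 higher and 1 lower for nerve and glia, 3 higher and 2 lower for serpins, 2 higher for duct growth, 1 higher and 1 lower for WFDC and SPINT inhibitors, 1 lower for RNases and 0 for the others.

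Among genes with at least 1 CPM in HET or KO and an ordinary symbol, the largest rises from HET to KO were Ren1 (2.78 ± 0.55), the relaxin receptor gene Rxfp1 (2.50 ± 0.50), Dusp13 (2.45 ± 0.55), Ctla2a (2.10 ± 0.46, and 1.45 without KO-739), the complement gene C2 (2.04 ± 0.40), Grp (1.96 ± 0.35) and Art5 (1.91 ± 0.47). Next came Efcab9 (1.42 ± 0.35), Scube2 (1.36 ± 0.25) and the transcription factor gene Gata6 (1.33 ± 0.30). The largest falls were Kap (-2.21 ± 0.40), Ugt1a1 (-0.86 ± 0.19), Mcoln3 (-0.80 ± 0.18), Car4 (-0.75 ± 0.16), and Bglap3 (-0.70 ± 0.12), followed by Cadm2 (-0.69 ± 0.17), Piwil2 (-0.65 ± 0.16), Slc15a2 (-0.64 ± 0.14), Prr27 (-0.63 ± 0.14) and Pipox (-0.61 ± 0.15). Below 1 CPM, Evx1os had -1.96 ± 0.44. Ugt1a1 shares exons with its neighbours and is uncertain. The smallest p-values belonged to Aoc3 (0.60 ± 0.08), Tenm3 (0.64 ± 0.09), Pxdn (0.62 ± 0.09), the chemokine gene Cxcl12 (0.39 ± 0.06) and Sh3pxd2a (0.52 ± 0.08) among rises. Among falls they belonged to Amdhd1 (-0.59 ± 0.09), Skap1 (-0.32 ± 0.06), Baiap2l1 (-0.29 ± 0.06), Bglap3 and Kap.

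The number of KO versus HET genes with an adjusted p under 0.05 (edgeR) was 381, with 313 higher and 68 lower, and 36 of them differed by at least 2-fold (29 higher, 7 lower). By camera 23 of 42 lists passed, 0 with an estimated correlation, and 16 passed fry. Of those 16, camera did not call the PLAG family (fry adjusted p = 0.0444), caput (0.0444) and androgen response lists (0.0428), all lower, or testis somatic cells (0.0443, higher). Of the 23 lists 14, and all 59 named genes with a call, lost it in at least 1 fit without a library. Skeletal muscle was at 0.512 without KO-739, and without KO-695 cell cycle was at 0.121, ciliated cells at 0.067 and beta-defensins at 0.204. Without HET-692, HET-693, HET-715, HET-718 or HET-735 the count was 757, 6, 3, 31 or 0, and without KO-694, KO-695, KO-696, KO-738 or KO-739 it was 227, 154, 5, 2443 or 172. By edgeR it was 0 in a fit of the HET and KO libraries alone, 0 among the animals numbered 700 and above and 0 without HET-735 (3432, 2026 and 3322 at an unadjusted p under 0.05). Other tools were not run there. On all libraries DESeq2 gave 1258 and limma voom 1909.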

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

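The tests of the patterns weighed here were chosen after their results were seen, except the counts over other splits of the libraries. For the fibroblast and macrophage genes, the test with the number range as a term took the place of the comparison among animals numbered 700 and above, which had left the question open, after both values were seen. Of 576 groups of 5 libraries checked for a library far from the other 4 (Dixon's ratio above 0.71), 52 held one (9.0%), where chance gives about 1 in 20 for normally distributed values. The share was 5.6% of 126 groups for list scores and 9.9% of 444 for genes. Genes were checked on untransformed CPM, and many were named for large changes, so that rate need not hold for them. Of the 52, 15 were in KO-738, 7 in KO-739 and 7 in WT-720.
The share of ribosomal RNA genes was 1.289% in KO-738 against 0.052% to 0.088% in the other KO libraries. Among list scores, the junction score was -0.08 in WT-726 and -0.31 in KO-739, the endothelial score -0.23 in WT-723, the macrophage score 0.02 in KO-738 and the RNase score -0.04 in HET-692, each below the others of its genotype. The skeletal muscle score was 1.8 in HET-718 and 7.3 in KO-739, above the others. The genes with 1 library far above the other 4 of its genotype are given here with its CPM. HET-692 held Adam5 (6.51), Fabp9 (5.98), Ldhc (14.1) and Pmp22 (63.3). HET-693 held Tmem254c (4.02). HET-718 held Gtsf1l (0.546) and Myh1 (11.5). HET-735 held Gpx6 (68.1). KO-694 held Get1 (3.53). KO-695 held Adipoq (17.9) and Ccnb1 (16.7). KO-738 held Amdhd1 (7.31), Azgp1 (5.42), Baiap2l1 (32.4), Gpx3 (3480), H2-Eb1 (10.5), Pappa2 (4.55) and Treh (2.63). KO-739 held Actn3 (165), Car3 (803), Ctla2a (236) and Myh1 (899). WT-719 held Car3 (20) and Lpl (18.4). WT-720 held Adam23 (16.1), Aqp1 (84.5), Ctla2a (26.6), Hoxd10 (8.44), Myh1 (1.82), Pmp22 (56.6) and Rxfp1 (1.22). WT-723 held Rpl39l (0.805). WT-726 held Kap (2.41) and Scn7a (10.9). The genes with 1 library far below the other 4 of its genotype are given here with its CPM. KO-695 held Dnajb9 (118). KO-738 held Adam23 (11.4), Cx3cr1 (9.94), Igf1 (32.5), Mpeg1 (17.2), Scube2 (1.22) and Tenm3 (10). KO-739 held Rpl27 (146). WT-719 held Vwa2 (67.4). WT-726 held Cnmd (0.163).

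In the rise of fibroblast, endothelial and macrophage genes in KO against WT, weighed first, the mean score of the 3 lists rose by 0.62 and the smooth muscle score by 0.10, and their difference of 0.53 (exact permutation p = 0.0159 over 252 arrangements) argues against a lower share of epithelial cells raising all other types alike; in KO against HET they rose by 0.50 and 0.33, and the difference of 0.17 (exact permutation p = 0.1667) does not exclude it there. With all libraries thinned to 1 depth, 37 members were called against 40 of 54, which argues against depth, and with the adipocyte score as a term the KO effect on the mean score was 0.66 (SE 0.13) against 0.62 (SE 0.11), which argues against attached fat, although 522 genes and 25 of the members were then called. Among the animals numbered 700 and above, the endothelial scores of KO-738 (0.44) and KO-739 (0.81) exceeded the highest WT score of 0.09 (exact permutation p = 0.0476, the smallest that 21 arrangements allow). This argues against the split at 700 as the cause for the endothelial genes. Both KO animals are numbered above every WT animal, so a difference tied to the numbers in another way is not removed. For fibroblast and macrophage genes the KO effect on the score was 0.55 (SE 0.15) with the number range as a term against 0.64 (SE 0.13) without it, which argues against the number range as the whole cause if it acts alike in HET and KO, although the calls fell from 30 to 4 of 42 members (medians 0.69 and 0.62) and the 2 KO animals numbered 700 and above, at 0.07 and 0.88 against at most 0.14 in WT, do not decide it alone (exact permutation p = 0.0952). A part due to the number range, an effect of genotype, a change within the cells that rose and any difference in litter or collection stay open.

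Germ cell transcripts were weighed second. Within HET and within KO, animals numbered below 700 (2 HET, 3 KO) had higher germ cell scores than the others, by 0.90 on average (exact permutation p within genotype = 0.01 over 100 arrangements, the smallest it can give), consistent with a difference tied to the number range, such as more sperm or testis cells left after the wash. Among the animals numbered 700 and above the KO minus WT difference was -0.18 (exact permutation p = 0.5714), and over all animals it was 0.65 (exact permutation p = 0.127). Single genes named for their rise (Ldhc, Fabp9, Meig1, Ddx4 and Akap3) nonetheless lay above every WT library in KO-739, which is numbered above 700. KO-738, also numbered above 700, lay within the WT range for each of these genes. The genes were named for their rise in a comparison that includes KO-739. Whether their rise goes beyond the animals numbered below 700 thus rests on KO-739 alone and stays open. Because all WT animals are numbered above 700, a part due to genotype stays open, and the meaning of the numbers is unknown.

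For the KO against WT genes, 2 of 100 splits (of 126 possible) gave at least the real count of 1163, the real one included. The highest other gave 1238, in the split that exchanges KO-738 with WT-719. A count this large was rare among the splits, but a wrong grouping exceeded it, so chance is not excluded. Exchanging KO-738 with WT-723 or WT-726 gave 1055 or 1002, and with WT-709 it gave 202, while the exchange with WT-720 was not drawn. This points to a structure of the samples around KO-738. This library lay within the WT range on the first principal component and in the fibroblast and macrophage scores. It lay outside that range for Evx1os (0.063 CPM against at least 0.402, near the floor of detection) and the endothelial score (0.44 against at most 0.09), measures picked after their values were seen. Its Plag1 level of 9.38 CPM lay below the WT range of 11.96 to 14.03 CPM, but within the HET range of 8.12 to 11.84 CPM. Ribosomal RNA genes took 1.289% of its counts, against 0.052% to 0.088% in the other KO libraries. Whether its genotype label or its dissection differs from the other KO animals stays open. For the 18 lists of this comparison, 2 of 100 splits gave as many and the highest other gave 19, so a number of lists this large was also rare among the splits. This does not extend to single lists: the other splits gave a median of 9 lists, and 99 of them gave at least 1. For the HET against WT genes the real count is 0, which 100 of 100 splits reach by construction (highest other 1), so the splits decide nothing. For its 11 lists, 5 of 100 splits gave as many (highest other 13), and chance could not be excluded. For KO against HET, 3 of 100 splits gave at least the real 381 genes. The split that exchanges HET-693 with KO-738 gave 393, and the split that exchanges HET-692 with KO-738 gave 2274. The latter is several times the real count and so again points to a structure of the samples. For the lists, 1 of 100 splits, the real one, gave 23 (highest other 20). Counts this large were thus rare among the splits, which does not exclude chance. The gene count was also 0 without HET-735 and in a fit of the HET and KO libraries alone. The other splits gave a median of 11 lists here, and 99 of them gave at least 1. For HET against the midpoint the real count is also 0, and the 100 of 100 splits that reach it decide nothing. The highest other gave 1269, with WT-726, HET-693, HET-715, HET-735 and KO-739 in the HET position, of which 1 is numbered below 700. The split with exactly the 5 animals numbered below 700 there came next. These splits point to a structure of the samples, and the number range does not account for the highest.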

How the results depend on the processing

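The fits without libraries over 1% ribosomal RNA genes and at equal depth were chosen after the data were seen. No paired analysis was possible because no 2 groups share an animal number. Each named gene and each list that passed camera counts once per comparison here. Of 4997 values under alternatives for 180 such results of named genes, 3688 kept direction and side of the threshold, 1291 kept direction but no longer passed, 17 newly passed and 1 reversed. Of 1092 values for 52 such results of lists these numbers were 897, 190, 0 and 5.

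The number of KO versus WT genes was 1163, and 1982 by DESeq2, 287 in a fit of the 2 groups, 176 with the number range as a term, 0 among animals numbered 700 and above (edgeR, 3073 unadjusted) and 2722 without the libraries over 1% ribosomal RNA genes. It was 318 to 2923 with 1 library left out. The number of HET versus WT genes was 1 by DESeq2 and 0 to 0 with 1 library left out (edgeR, 854 unadjusted on all libraries, voom 0). The number of KO versus HET genes was 381, and 1258 by DESeq2, 1909 by voom, 0 in a fit of the 2 groups (3432 unadjusted), 0 among animals numbered 700 and above (2026 unadjusted), 1660 without the libraries over 1% and 0 to 2443 with 1 left out. For HET versus midpoint of WT and KO genes DESeq2 gave 24, voom 1 and leaving out 1 library 0 to 0 by edgeR (1522 unadjusted on all libraries). Fewer libraries enter the fits of 2 groups and of animals numbered 700 and above. A fit of 2 groups also takes the genotype left out from the estimate of the spread, and libraries varied most within KO. For none of the changes was the cause tested. Plag1 level, KO versus WT was -0.449 (adjusted p 0.168) among animals numbered 700 and above and -0.651 to -0.547 with 1 left out, HET versus WT -0.389 to -0.260 and KO versus HET -0.345 to -0.209.

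Lists passing in KO versus WT were 0 by estimated correlation and 17 to 20 with 1 library left out. In HET versus WT they were 0 by estimated correlation, 0 by fry and 6 to 14. In KO versus HET they were 0 by estimated correlation, 11 among animals numbered 700 and above and 17 to 25. Among animals numbered 700 and above these reversed: Plagl2, KO versus WT at 0.005 (adjusted p 0.982), and, given by camera adjusted p, list Sperm and germ cell transcripts, KO versus WT (0.0912), list Ciliated efferent duct, KO versus WT (0.759), list Cell cycle, HET versus WT (0.844, and 0.671 with the number range term) and list Sperm and germ cell transcripts, KO versus HET (0.0177, now lower in KO). In each the cause was not tested. Genes removed by a filter gave no value there. With all libraries thinned to 1 depth, KO versus WT genes numbered 939.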

Other observations

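The tests of the clock genes were prompted by Dbp and Per2, and the tests by animal number, of Evx1 and of the Plag1 region were chosen after results were seen; the prediction for the other clock genes was set before their values were seen. Evx1os and Evx1, neighbours on chromosome 6 that were chosen after their values were seen, were lowest in KO, with HET between WT and KO. Evx1os had 0.76 ± 0.27 CPM (SD, n = 5) in WT, 0.24 ± 0.09 in HET and 0.06 ± 0.03 in KO, with 0.063 CPM in KO-738, and its log2 fold change was -3.61 ± 0.38 (SE) for KO against WT (edgeR adjusted p = 0.000821) and -1.96 ± 0.44 for KO against HET (0.0348), while HET against WT, at -1.65 ± 0.31, did not pass (0.981). Evx1, a homeobox gene, had 0.59 ± 0.22, 0.17 ± 0.08 and 0.05 ± 0.06 CPM, and -3.53 ± 0.57 for KO against WT (0.00436; -4.51 without KO-738). Both are near the floor of detection, overlap, and cannot be told apart without a stated strand setting.

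Lower Dbp and Per2 in KO may reflect a shift of the clock phase at collection. Of the genes not used to find the pattern, the mean of 8 of the Per and Nr1d arm changed by -0.29 (exact permutation p = 0.0079) and that of 5 of the Arntl arm by 0.29 (exact permutation p = 0.0159), and the difference between the arms, -0.58, had an exact permutation p of 0.0079, the smallest that 252 arrangements allow. In HET the difference was -0.26. Animals numbered below 700 had a lower difference within HET and KO, by -0.36 (exact permutation p = 0.01). The number range could therefore carry a part. Among animals numbered 700 and above KO was still lower by -0.33 (exact permutation p = 0.0476), which argues against the split at 700 as the whole. The KO animals there are numbered above every WT animal, so a difference tied to the numbers in another way is not removed. Of them, KO-738 had arm scores of -0.08 and 0.06, near WT-709 (-0.04 and 0.07), and KO-739 had -0.28 and 0.24. Bhlhe41 of the first arm (0.10) and Cry1 of the second (-0.06) had the opposite sign. Collection time and genotype stay open.

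Near Plag1, within 1 Mb 1 of 11 tested genes was called in KO against WT, within 10 Mb 2 of 63 (3.2% against 6% elsewhere, Fisher's exact p = 0.589) and within 20 Mb 5 of 97 (Fisher's exact p = 1). Across 19388 genes, which are not independent replicates, the log2 fold changes of HET and KO against the shared WT had r = 0.496, where 20 simulations of unchanged groups gave 0.512 and comparisons with different WT libraries in 20 splits gave 0.203. The covariance was 0.0326 against 0.0236 for unchanged groups, a difference of 0.009, and 0.0169 with split WT. The simulations used 1 dispersion per gene for all genotypes, although libraries varied most within KO. They may therefore misstate the part that comes from the shared WT. With different WT libraries no control is shared, and unchanged independent groups would give no correlation on average. The simulated r of 0.512 thus does not exclude a change shared by HET and KO, whose cause was not tested.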
